A study of Drosophila melanogaster with 2 samples.

How the data were processed

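The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) on Drosophila melanogaster. Per the labels, the flies were transgenic and carried Ets96B, a transcription factor of the ETS family, fused at its C terminus to green fluorescent protein (eGFP). The immunoprecipitation used an antibody against GFP, although another field of the labels names the antibody by the tagged factor. Chromatin came from whole prepupae of both sexes aged 24 h. The labels place both libraries in 1 group and number them as biological replicates 2 and 3. A control alignment enters the deposited peak calls, and its reads were not analysed here.

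The authors deposited 4 peak lists on the dm6 assembly in narrowPeak format: 1 for each replicate, 1 pooled and 1 reproducible. Per the labels and the deposited description files, each replicate list derives from that replicate's alignment and a control alignment. The pooled list derives from both alignments and the control. The reproducible list keeps peaks past an irreproducible discovery rate (IDR) threshold, computed from the replicate lists and the pooled list. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each peak carries the authors' signal value, as deposited, which was used to rank and describe peaks within a list and was correlated between the replicate lists over shared peaks. Each peak also carries a deposited −log10 q-value, and in the reproducible list it was 4.42 for all 8015 peaks. It therefore ranked no peak. Of the 8015 reproducible peaks, 7875 covered distinct intervals, so some intervals carry more than 1 summit and each summit was counted.

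Both replicate lists and the pooled list held exactly 30000 peaks. The number of peaks in a replicate list therefore does not measure its depth, and the read depth is unknown from these files. All 8015 reproducible summits were found in the pooled list, where they held ranks 1 to 8015 by signal value. Peaks and genes are not replicates. Intervals and p-values across them describe these lists, and the replicate error, where given, comes from repeating a result on each replicate's own 8015 strongest peaks. The comparisons with matched lists and G+C-matched windows, the positions around TSSs, the words by promoter class and the shared promoters were not repeated by replicate. Coordinates are 1-based on dm6.

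Annotation came from Ensembl release 115, with 19630 transcription start sites (TSSs) of 13968 protein-coding genes on the chromosome arms. The genome sequence of the same assembly was the RefSeq copy. Each summit was assigned to 1 class in the order promoter (within 500 bp of a protein-coding TSS), 5' UTR, coding exon, 3' UTR, intron, other transcript and intergenic. Class shares were compared with 1000 random placements of the summits within their arms. Overlaps between lists needed at least 1 bp and were compared with 100 random placements. Signal values of peaks that overlapped 1 to 1 were correlated across peaks, with 1000 random pairings. Medians of signal values were compared by a two-sided permutation test with 100000 resamples. Binomial intervals are exact Clopper-Pearson intervals and densities have exact Poisson intervals, all at 95%, and cover counting error only.

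A gene counted as occupied when a reproducible summit lay within 500 bp of any of its TSSs. Occupancy of 23 gene lists was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg (BH) adjustment over lists at 0.05. Each list was also placed among 10000 random lists matched on number of TSSs and decile of gene length. Of the list symbols, 4 matched no protein-coding gene in the annotation, and 2 of those name non-coding RNA genes. Older symbols were resolved through RefSeq synonyms, and 3 ambiguous ones (Dl, Tor and Trh) were resolved by hand after the data were seen. For 19 sequence words, the share of peaks with the word within 50 bp of the summit was compared with windows centred 400 bp to either side. The test was an exact sign test against the flank at the lower coordinate, adjusted over words. A second background was random windows matched on arm, promoter class and decile of G+C content, 5 per peak, compared by Fisher's exact test. These windows were first drawn from 60 candidate positions per peak. The number was raised to 150 when exact matching of G+C was added, after the first value had been seen, and the matched ETS share moved from 2.92% to 3.07%. Over 11 draws it ran from 2.86% to 3.09% with 60 candidates and from 2.83% to 3.16% with 150. With the same change, the closing test of G+C content as the cause of the ETS deficit was made to need both backgrounds, and its outcome was the same with either. Calls against matched windows were counted over the 11 draws. The control word for ETS is the ETS word read backwards without complementing.

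The tests, lists, words, most alternatives and the rule for naming genes were fixed before the data were examined. The rule takes the 20 peaks of highest signal value, named by the nearest TSS, and Ets96B itself. It adds up to 4 members of each list with the strongest peaks, and every member of lists of up to 8 genes. For lists tested higher than the background it adds the 2 unoccupied members with the most TSSs. Of the genes this rule takes, 1 was left out and is not reported here. Genes with the most summits were chosen after their values were seen. Alternatives covered the overlap rule, the promoter window, the 4007 strongest reproducible peaks, each replicate alone, other backgrounds and other word windows. Giving each summit only to its nearest TSS, matching the exact number of G and C bases, and repeating the draws of matched windows, were added after the data were seen.

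The code was tested on simulated data. Over 20 sets of randomly placed summits, 3 of 460 tests of gene lists and 0 of 380 tests of words passed the threshold. Simulated lists of 40 genes were called in 20 of 20 draws with 40% of members occupied, and in 0 of 20 draws with 30%. The number of occupied members was the same in each draw, so these counts locate the threshold and are not detection rates. An ETS word planted in 2% of 8015 randomly placed summits was called in 20 of 20 draws. Those summits lacked the low G+C content of the measured ones, so this does not show that such a share would be found there. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. No comparison between groups was possible because the series has 1 group.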

Results

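Ets96B-eGFP binding was mapped in whole Drosophila melanogaster prepupae of both sexes, 24 h of age, by ChIP-seq against the GFP tag. Ets96B is the fly member of the PEA3 subfamily of ETS transcription factors. The data comprised 2 biological replicates of 1 group, numbered 2 and 3, so the comparisons possible were between replicates, between regions and between gene groups. The replicate lists and the pooled list held 30000 peaks each. The reproducible list held 8015 peaks with a median width of 310 bp. Signal values in that list ran from 148 to 5811, with a median of 293. They are the authors' own scores and order peaks within the list.

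The first question was whether both replicates marked the same regions. Of the replicate 2 peaks, 77.1% (95% CI 76.6 to 77.6) overlapped a replicate 3 peak. In the other direction the share was 75.4% (74.9 to 75.9). Random placements gave means of 14.3% and 14.2%. Over the 12775 peaks that overlapped 1 to 1, signal values correlated across peaks with a Spearman rho of 0.852. The 1000 random pairings gave rho between -0.029 and 0.026 (p = 0.0010, the smallest they can give). The reproducible list holds the first 8015 ranks of the pooled list, which derives from both replicates. Its overlap with the replicate lists therefore follows largely from its making and is no test of agreement. Of its 8015 peaks, 7964 overlapped a peak in replicate 2 and 7952 in replicate 3, and 98.6% (98.3 to 98.8) did so in both. The median rank of the matching peaks was 3892 in replicate 2 and 3818.5 in replicate 3, and the lowest ranks were 28012 and 26790. With summits required to lie within 100 bp, the overlap between replicates was 56.8% in both directions.

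The strongest reproducible peak lay 30 bp upstream of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter. It covered X from 2703660 to 2704110 with its summit at 2703882, a signal value of 5811, rank 3 in replicate 2 and rank 1 in replicate 3. The second lay in an intron of CG11050 (FBgn0031836) on 2L, with its summit at 6612710 and a signal value of 5309. The third lay 323 bp from the nearest TSS of larp (FBgn0261618), an RNA-binding protein gene, with its summit at 28326587 on 3R. Of the 20 strongest peaks, 11 were in promoters, 5 in introns, 2 in other transcripts and 2 were intergenic. The promoter peaks lay 11 to 323 bp from a TSS. They included those of CG18549, CG14100, PNPase, CenG1A, mRpS10, CG13921, CG9147, osp and Chro, the last a chromodomain protein gene. The intronic peaks were at CG32772, at Lk6, a kinase acting on the translation factor eIF4E, and at osa, a subunit of the Brahma remodelling complex. The peak nearest to cbt, a zinc-finger factor gene, lay 1399 bp from its TSS and inside an intron of ush. A pair of peaks nearest to CG4004 lay 5006 and 6055 bp from its TSS, and the intergenic peaks lay 3759 bp from CG31668 and 11976 bp from CG13323. All 20 ranked 25 or better in both replicate lists, and 0 of 20 held the ETS word C[AC]GGAA[AG] within 50 bp of the summit. Over all 8015 summits the share with this word was 2.45%, so 0 of 20 shows no difference from the whole list.

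Promoters held 2456 of the 8015 summits, or 30.6% (29.6 to 31.7), which was 2.68 times the 11.4% of random placements. Introns held 44.4% (43.3 to 45.5) against 39.2%, and intergenic sequence held 21.01% (20.1 to 21.9) against 28.0%. Coding exons held 9 summits, or 0.112% (0.051 to 0.213), against 13.9% at random. The 3' UTRs held 59 summits, or 0.736%, against 4.51%. Each of these differences had a permutation p = 0.0020, the smallest that 1000 random placements can give. The strongest 8015 peaks of replicate 2 had 32.5% of summits in promoters and those of replicate 3 had 30.7%. Within promoters, 78.5% (76.8 to 80.1) of summits lay upstream of the nearest TSS, with a median position of -128 bp. The bin from -250 to -51 bp alone held 1236 of them. Against the bases covered by all pooled peaks, the promoter fold was 1.34 and introns turned to 0.960 of the background. That background includes the reproducible peaks themselves, which draws the folds closer to it, so it is no contrast with the other peaks.

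**Figure D1:**
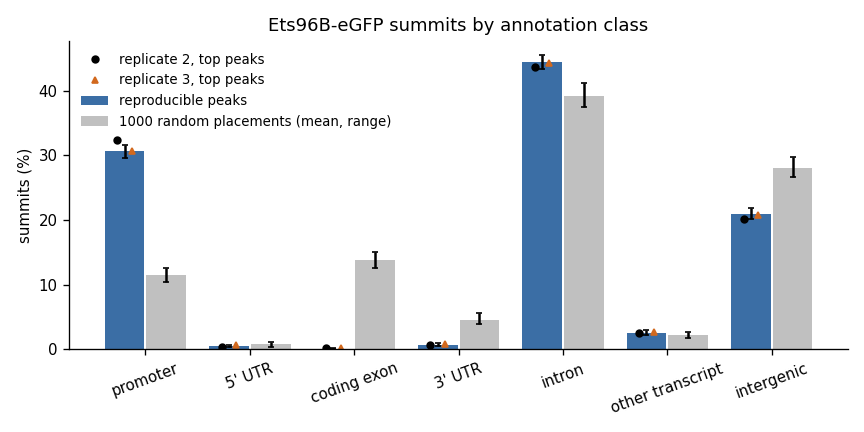
Share of summits (%) in each annotation class for the 8015 reproducible peaks (blue bars, exact 95% intervals) and for random placements within arms (grey bars, mean with the range of 1000 placements). Points give the 8015 strongest peaks of each replicate. Promoters stand at 30.6% against 11.4%, and coding exons at 0.112% against 13.9%.

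By chromosome arm, 3L carried the highest density of summits, with 65.7 per Mb (62.7 to 68.7). It was followed by X with 63.1 (59.9 to 66.4), 2L with 62.5 (59.3 to 65.8), 3R with 57.0 (54.4 to 59.6) and 2R with 53.9 (51.1 to 56.9). The small arm 4 carried 24 summits, or 17.8 per Mb (11.4 to 26.5). Per 100 annotated TSSs, 4 carried 16.9 (10.8 to 25.1), 2R 33.8 (32.0 to 35.6) and 3L 48.8 (46.6 to 51.1). On Y there were 0 summits on 3.67 Mb, and how well reads map there was not examined. Arm 4 had 31 summits among the strongest 8015 peaks of replicate 2 and 19 among those of replicate 3. Promoter peaks had a median signal value of 301 (quartiles 200 to 585) and the other peaks 289 (198 to 497). The ratio of 1.04 did not pass the two-sided permutation test (p = 0.051). It turned to 0.973 with a promoter window of 200 bp and to 0.988 with replicate 2 alone (permutation p = 0.25 and 0.53), and passed at 1.045 with 1000 bp (permutation p = 0.026). Promoters made up 44.4% (39.99 to 48.9) of the 500 strongest peaks and 28.0% (24.1 to 32.2) of the 500 weakest.

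Which genes carried these promoter summits was examined next. Of 13968 protein-coding genes, 2863 (20.5%) had a reproducible summit within 500 bp of a TSS. The share was 21.5% with the strongest peaks of replicate 2 and 20.4% with those of replicate 3. Of the promoter summits, 772 lay within 500 bp of TSSs of more than 1 gene. As a result, 1446 of the 2863 occupied genes had only summits they share with a neighbour. Of the 23 lists, 8 were occupied more often than other genes and 3 less often. Against random lists matched on TSS number and gene length, 3 were higher and 3 lower.

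Cytosolic ribosomal protein genes had the highest share of the 23 lists. Of 86 such genes, 51 were occupied (59.3%, 48.2 to 69.8), against 20.3% of other genes, an odds ratio of 5.74 (Fisher's exact test with Benjamini-Hochberg, BH, adjusted p = 4.2e-14). Matched random lists averaged 21.8%. The strongest summits were at RpL32 (790 signal, summit 30046326 on 3R), RpL34b (737 signal) and RpS20 (517 signal), while RpL7A and RpL17 had none. Replicate 2 alone gave 47.7% (odds ratio 3.35) and replicate 3 alone 61.6% (6.36). Among the 4007 strongest peaks the odds ratio was 1.49 and the call was lost (BH-adjusted exact p = 0.27). Of 73 mitochondrial ribosomal protein genes, 28 were occupied (38.4%, 27.2 to 50.5, odds ratio 2.43, BH-adjusted exact p = 0.0019), against 11.5% in matched lists. They included mRpS23, mRpS10, mRpL41 and mRpL23, with ranks 15, 16, 36 and 76, while mRpL42 and mRpS14 had no summit. The peak counted for mRpS23 is the one nearest to CenG1A. With each summit given only to its nearest TSS, 11 of the 73 remained occupied and the odds ratio was 0.973 (BH-adjusted exact p = 1). Among the 4007 strongest peaks the call was also lost (odds ratio 1.66, BH-adjusted exact p = 0.20). Oxidative phosphorylation genes were not called, with 13 of 89 occupied (odds ratio 0.662, BH-adjusted exact p = 0.24). Their strongest summits were at ND-ASHI, ND-MWFE, ND-42 and ND-51.

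Genes of the autophagy and cell death list were occupied in 15 of 37 cases (40.5%, 24.8 to 57.9). The odds ratio was 2.65 (BH-adjusted exact p = 0.016). Examples were hid, with a signal value of 1552 at 18185971 on 3L, Atg2, Atg17 and Atg7, and Diap1 and Atg16 had none. This call also held against matched lists, which averaged 20.7% (BH-adjusted permutation p = 0.037), and it was lost with a TSS window of 200 bp (BH-adjusted exact p = 0.071). The ecdysone response list had 16 of 39 genes occupied (41.03%, 25.6 to 57.9, odds ratio 2.71, BH-adjusted exact p = 0.014). It included E23, an ABC transporter gene, with a signal value of 2205, the nuclear receptor gene Eip75B with 1323, mamo with 1102 and Eip93F with 748. Blimp-1 and Eip78C had no summit at a TSS. Matched lists averaged 35.95%, and the ecdysone call was lost against them (BH-adjusted permutation p = 0.68) and with a TSS window of 200 bp (BH-adjusted exact p = 0.19).

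Among signalling genes, 20 of 48 in the Wnt, Hedgehog, Dpp and Hippo list were occupied (41.7%, 27.6 to 56.8, odds ratio 2.78, BH-adjusted exact p = 0.0034), with sgg, nkd, Mer and ft strongest and none at sd or arm. In the receptor tyrosine kinase and Ras list, 18 of 48 were occupied (37.5%, 23.95 to 52.6, odds ratio 2.34, BH-adjusted exact p = 0.016). The strongest were Shc with a signal value of 1715, puc, a MAP kinase phosphatase gene, with 1680, the EGF ligand gene spi with 1678 and aos with 1136, and Pvf3 and Pvr had none. Against matched lists neither was called (BH-adjusted permutation p = 0.092 and 0.35). The Wnt list was also lost among the 4007 strongest peaks (BH-adjusted exact p = 0.21), and the Ras list with a TSS window of 200 bp (0.18) and with replicate 2 peaks alone (0.075). Fat body and larval serum genes had 10 of 22 occupied (45.5%, 24.4 to 67.8, odds ratio 3.24, BH-adjusted exact p = 0.017). Fer1HCH and Fer2LCH, the ferritin chains, share 1 summit there. Hnf4 and Apoltp followed, and ACC and Fbp2 had no summit. Glial genes had 7 of 15 occupied (46.7%, 21.3 to 73.4, odds ratio 3.3998, BH-adjusted exact p = 0.043), with loco, moody, Gli and wrapper strongest and none at Eaat1 or Gs2. Neither of these calls held with either replicate alone, among the 4007 strongest peaks or against matched lists. With a TSS window of 200 bp the glial odds ratio was 0.980, and the fat body call was lost (odds ratio 1.42).

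**Figure D2:**
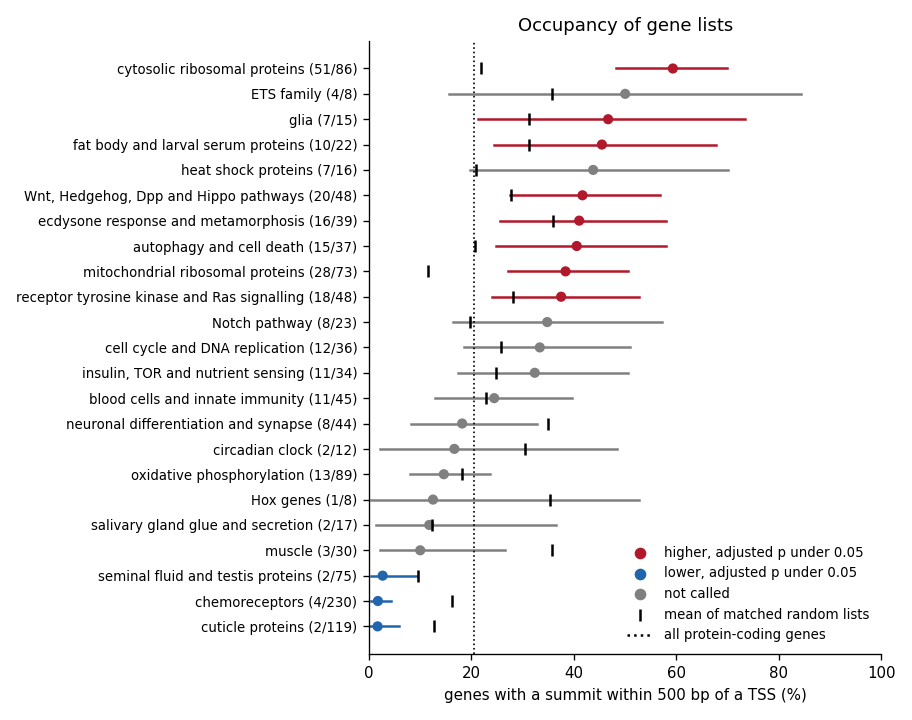
Share of each list's genes (%) with a reproducible summit within 500 bp of a TSS, with exact 95% intervals and counts beside each name. Red and blue mark lists called higher and lower than other genes, black ticks the mean of matched random lists and the dotted line all protein-coding genes (20.5%). Cytosolic ribosomal protein genes stand at 59.3% and cuticle protein genes at 1.68%.

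Genes of terminal sensory, cuticular and reproductive products were seldom occupied. Chemoreceptor and odorant-binding genes had 4 of 230 (1.74%, 0.476 to 4.39, odds ratio 0.067, BH-adjusted exact p = 2.1e-16), namely Obp83g, Obp99b, Gr77a and Obp83cd. Cuticle protein genes had 2 of 119 (1.68%, 0.204 to 5.94, odds ratio 0.066, BH-adjusted exact p = 1.1e-08), Cpr72Ea and Cpr12A. Both were also below the matched lists, which averaged 16.2% and 12.7% (BH-adjusted permutation p = 0.0011 for each, from an unadjusted 0.0002, the smallest that 10000 lists can give). With replicate 2 alone the odds ratios of both were 0.031. Seminal fluid and testis genes had 2 of 75, Mst85C and Sfp26Ad (odds ratio 0.106, BH-adjusted exact p = 5.8e-05), and were not called against matched lists (9.58%, BH-adjusted permutation p = 0.092). Their odds ratio was 0.049 with replicate 2 alone and 0.162 with replicate 3 alone. Muscle genes had 3 of 30, Msp300, sls and Tm1, which was not called against all genes (odds ratio 0.430, BH-adjusted exact p = 0.24). Against matched lists, which averaged 35.7%, muscle was lower (BH-adjusted permutation p = 0.0092). Neuronal and synaptic genes had 8 of 44, led by elav with a signal value of 1711, and then Nrx-1, Rbp9 and CadN. They were not called (odds ratio 0.862, BH-adjusted exact p = 0.93), nor against the matched 34.97% (BH-adjusted permutation p = 0.060).

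The remaining lists did not pass the test. Heat shock protein genes had 7 of 16 (43.8%, 19.8 to 70.1, odds ratio 3.02, BH-adjusted exact p = 0.058), with Hsp27 at rank 22 and a signal value of 3726, followed by Hsp26, Hsp22 and Hsp83. This list was called with a TSS window of 200 bp (BH-adjusted exact p = 0.048), with whole gene bodies (0.040) and with each summit given only to its nearest TSS (0.015). The ETS family had 4 of 8 (odds ratio 3.88, BH-adjusted exact p = 0.10), and passed with each summit given only to its nearest TSS (odds ratio 5.50, BH-adjusted exact p = 0.045), an assignment chosen after the data were seen. With replicate 2 alone its odds ratio was 2.19 and against matched lists 1.80, and neither passed. Its occupied members were pnt with a signal value of 437, Eip74EF with 393, aop with 249 and Ets21C with 158. Ets96B, Ets65A, Ets98B and Ets97D had no summit at a TSS. Notch pathway genes had 8 of 23, led by E(spl)mdelta-HLH, numb, E(spl)m3-HLH and E(spl)m7-HLH, and were called among the 4007 strongest peaks (BH-adjusted exact p = 0.042) and with whole gene bodies (0.039). Cell cycle genes had 12 of 36, led by Dp, CycE, RnrS and Mcm2. Insulin and TOR genes had 11 of 34, led by Lpin at rank 40, Pi3K21B, bmm and mTor, and were called only with whole gene bodies (BH-adjusted exact p = 0.040). Blood and immune genes had 11 of 45, led by imd, cact, PPO3 and pll. Circadian genes had 2 of 12, cry and vri, and salivary glue and secretion genes 2 of 17, CrebA and fkh. Of the 8 Hox genes, abd-A alone had a summit, while lab, pb, Dfd, Scr, Antp, Ubx and Abd-B had none. From the Notch to the Hox list, BH-adjusted exact p ran from 0.10 for cell cycle (odds ratio 1.94) to 1 for the circadian (0.776) and Hox (0.554) lists. The circadian odds ratio turned to 1.22 with replicate 2 alone and 1.95 with replicate 3 alone, and the salivary value moved from 0.517 to 0.228 with replicate 2 alone, none passing the test.

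Sequence words at the summits were compared with the flanks of the same peaks. The ETS word was present at 196 of 8015 summits (2.45%, 2.12 to 2.81) against 4.005% of flanking windows. This was a fold of 0.611 (exact sign test, BH-adjusted p = 1.4e-05), with 0.597 in replicate 2 and 0.607 in replicate 3. The control word gave 1.83% against 3.24%, a fold of 0.565 (BH-adjusted exact p = 2.8e-06). The longer ETS site ACCGGAAGT occurred at 4 summits, and at 0 of the strongest 8015 of replicate 2, where it passed as lower (BH-adjusted exact p = 0.023). In promoter peaks the ETS word stood at 3.05% against 4.28% over both flanks, and in the other peaks at 2.18% against 3.89%. The sign test used the flank at the lower coordinate only. There, 74 promoter peaks held the word at the summit only and 88 in that flank only, which did not pass (BH-adjusted exact p = 0.49). In the other peaks these counts were 116 and 202 (BH-adjusted exact p = 4.4e-06). The flank at the higher coordinate was not tested. Whether these classes differed was not tested. Across 5 equal groups of peaks by signal, the ETS share was 1.87% (1.27 to 2.66) in the strongest and 2.74% (2.00 to 3.67) in the weakest, while the mean G+C content of the windows rose from 28.7% to 34.9%. The rank correlation of 0.020 did not pass the permutation test (p = 0.071). It passed with the strongest peaks of replicate 2 alone (rho = 0.037, permutation p = 0.00086). Neither test held G+C content fixed.

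Of the 19 words, 3 were more frequent at summits than in flanks and 8 less frequent. The homeodomain core TAATTA was present at 11.02% of summits against 5.41%, the GATA word at 1.71% against 0.973%, and the DRE word of housekeeping promoters at 0.524% against 0.225%. The CA repeat, both E-boxes, the Runt word, the early zinc finger word and the GAGA word were lower, besides the ETS and control words. The word GGTCACAC, at a fold of 1.47, did not pass in the main test. It passed as higher with replicate 2 alone (2.24), with replicate 3 alone (1.66) and with windows of 100 bp either side. It also passed against G+C-matched windows and windows of the same G and C number. With windows of 25 bp either side it did not pass (1.60, BH-adjusted exact p = 0.43). The summit windows were poor in G+C, with a mean of 31.8% (SD 9.23 over peaks) against 44.6% in the flanking windows. Against windows matched on G+C content, the order changed. In the main draw of these windows the GAGA word was higher at summits (1.71% against 0.626%, Fisher's exact test, BH-adjusted p = 8.2e-18) and TAATTA lower (11.02% against 12.2%, 0.011). The promoter word GGTCACAC became higher (0.449% against 0.207%, BH-adjusted exact p = 0.0027). GATA, DRE, the CA repeat, both E-boxes, the Runt word and the early zinc finger word were not called. The ETS word was lower, at 2.45% against 3.07% (BH-adjusted exact p = 0.011), and so was the control word, at 1.83% against 2.38% (0.011). Over 11 draws the matched ETS share ran from 2.83% to 3.16%, above the summit interval in all 11, but the ETS word passed the test in 8 (BH-adjusted exact p 0.0039 to 0.14). GAGA, GGTCACAC and TAATTA passed in all 11 and the control word in 10. The Runt word, at 2.81% to 3.15% of matched windows, passed as lower in 4, and the CA repeat and the CTCF word as higher in 5 and 6.

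**Figure D3:**
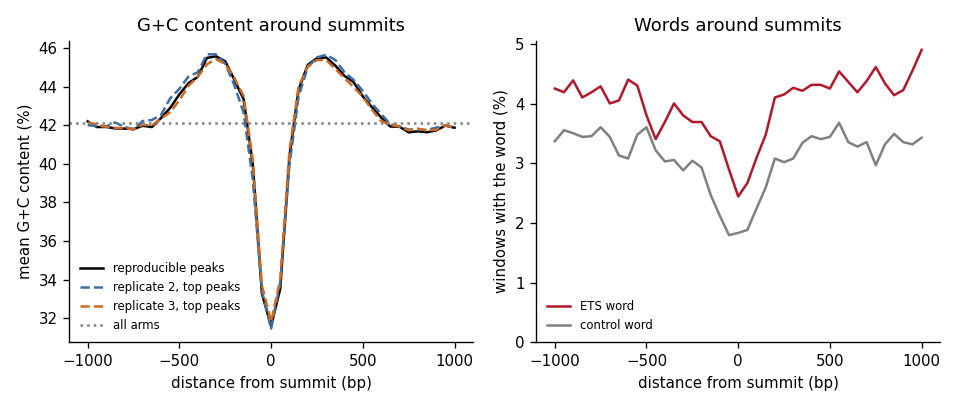
Left, mean G+C content (%) within 25 bp of each position against distance from the summit (bp) for the reproducible peaks and the strongest peaks of each replicate, with the mean of all arms dotted. Right, share of windows (%), 50 bp to either side of their centre, holding the ETS word or its control word. G+C content falls to 31.6% at the summit, and the ETS word to 2.45%.

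The locus of the tagged gene was examined last. Ets96B (FBgn0039225) lies on the plus strand of 3R from 24788054 to 24797955. Within the gene and 5 kb on either side, the reproducible list held 0 peaks, the pooled list 1, replicate 2 held 4 and replicate 3 held 2. The pooled peak had its summit at 24787371, in the promoter of the neighbouring gene CG5805 and 50 bp from its TSS. It ranked 8124 in the pooled list, just below the last reproducible rank of 8015, and 10162 in replicate 2 and 7943 in replicate 3. Replicate 2 had further peaks with summits at 24795227 (rank 3687) and 24795991 (rank 24212) in introns of Ets96B and at 24798810 (rank 3495) in an intron of Ude. The replicate 3 and pooled lists had no peak at these 3 positions.

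**Figure D4:**
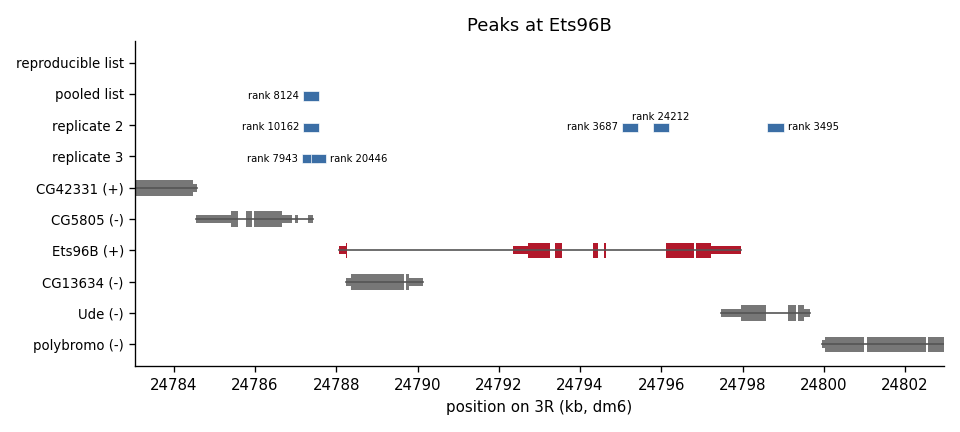
Map of the Ets96B locus on 3R (position in kb, dm6) with the peaks of the 4 lists (blue, labelled by rank within the list) and the genes (thick boxes coding, thin boxes untranslated, lines introns). The peak near CG5805 is in the pooled and both replicate lists, while the 3 peaks downstream are in replicate 2 alone.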

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

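Matching the exact number of G and C bases, giving each summit only to its nearest TSS, the repeat draws of matched windows and the number of candidate positions behind these windows were chosen only after results were seen. Of 437 alternative values over 68 results, 311 kept their direction and side of the threshold or stayed within the interval or count range, 41 lost a call, 22 gained one, 23 moved and 40 turned direction. Of those 40, 28 passed the test neither as reported nor under the alternative. Among the called lists, chemoreceptor and cuticle genes alone kept their calls in all alternatives run. No paired analysis was possible because the series has 1 group. With 2 replicates and no read depth, the spread between replicates is a range of 2 values. Where no cause is given, the cause was not tested.

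With 50% reciprocal overlap, 59.6% and 58.9% of replicate 2 and replicate 3 peaks were shared, with summits within 100 bp 56.8% and 56.8%, and among the strongest 8015 of each 83.5% and 81.9%. Reproducible peaks with a summit within 100 bp were 96.5% in replicate 2 and 97.9% in replicate 3. Against the bases of all pooled peaks, which include the reproducible peaks themselves, the fold was 0.960 in introns and 0.929 in other transcripts. With a promoter window of 1000 bp, the ratio of promoter to other signal passed the test at 1.045, and with 200 bp it turned to 0.973.

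Among the 4007 strongest peaks, 99.7% overlapped replicate 2 and 99.7% replicate 3, relative density was 1.19 on 3L and 1.02 on X, 1620 genes were occupied and 4 lists were higher. Odds ratios that lost their call were 1.49 for cytosolic and 1.66 for mitochondrial ribosomal proteins, 2.78 for glia, 2.25 for fat body and 1.76 for the Wnt list, and word folds 0.667 for early zinc finger and 1.41 for DRE. Fewer peaks were tested there.

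With a TSS window of 200 bp, 1896 genes were occupied and 4 lists were higher. Odds ratios were 1.91 for ecdysone, 1.90 for Ras, 1.42 for fat body, 2.37 for autophagy and, reversed, 0.980 for glia. The glial value was 2.73 at 1000 bp and 2.22 with gene bodies. With each summit given to its nearest TSS only, mitochondrial ribosomal proteins reversed to 0.973, since neighbours' summits no longer count. Against matched random lists, 3 lists were higher, with 1.24 for ecdysone, 1.53 for Ras, 1.93 for glia, 1.83 for fat body, 1.85 for Wnt and 0.259 for seminal fluid genes not called.

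Without each replicate in turn, 5 to 6 lists were higher, and 5 words in both cases. The words not called in the main list were GGTCACAC and the Stat word, the latter at folds of 1.236 with replicate 2 alone and 1.215 with replicate 3 alone. Odds ratios ran from 2.00 to 2.80 for Ras, 2.60 to 3.19 for glia and 1.82 to 2.53 for fat body. Folds ran from 0.676 to 0.764 for early zinc finger and 0 to 1.2 for the longer ETS site, and rho of rank and ETS word from 0.018 to 0.037. The ratio of promoter to other signal ran from 0.988 to 1.04, the circadian odds ratio from 1.22 to 1.95, the TEAD fold from 0.808 to 1.09 and the CTCF fold from 0.632 to 1.33.

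With word windows of 100 bp either side, 5 words were higher, and with 25 bp the folds were 0.783 for early zinc finger and 1.625 for DRE. Against G+C-matched windows and windows of the same G and C number, 3 and 3 words were lower. Reversed folds were, in that order, 2.73 and 2.499 for GAGA, 1.06 and 1.05 for CAGCTG, 0.901 and 0.878 for TAATTA and 1.26 and 1.27 for the CA repeat. Folds that lost their call were 0.959 and 0.927 for early zinc finger, 1.06 and 1.00 for DRE, 0.720 and 0.769 for CACGTG, 1.15 and 1.15 for GATA and 0.878 and 0.888 for Runt. In repeat draws ETS passed in 8 of 11 and Runt in 4 of 11.

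Turned values that passed no test were as follows. With gene bodies, odds ratios were 1.75 for neuronal, 1.08 for muscle, 2.53 for Hox and 1.81 for circadian genes, with a TSS window of 200 bp 0.979 for blood and 0.606 for Notch genes, and with each summit given to its nearest TSS only 1.22 for neuronal and 1.098 for circadian genes. Among the 4007 strongest peaks the circadian value was 1.53, and folds were 2.0 for the longer ETS site and 0.40 for CTCF, which stood at 0.927 with windows of 100 bp either side. Against G+C-matched windows and windows of the same G and C number, folds were 1.2 and 2.22 for the longer ETS site, 1.255 and 1.2497 for AP-1, 1.06 and 1.296 for CRE and 0.930 and 0.919 for Stat, and against the former 0.994 for the nuclear receptor half-site.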

Other observations

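Both tests of the ETS word, the repeat draws of matched windows, the counts at 6 other types of annotated feature, the comparison of peaks found in 1 replicate and the choice of genes and 7-base words by their values came only after the result was seen. Several long genes carried many reproducible summits. The adhesion gene kirre had 39 over 394 kb, Tet had 29 over 93.0 kb, SKIP had 26 and CG1677 had 24. These counts were not adjusted for gene length. At kirre the density was 0.989 per 10 kb, against 63.1 per Mb over the whole of X. Among these genes with the most summits, Mnt had 16 summits in 29.9 kb, or 5.36 per 10 kb, and tara had 16 in 34.7 kb, or 4.61 per 10 kb; density was not ranked over all genes. Eip75B had 16 and E2f1 15. Transposable element copies were rarely near a summit: 49 of 5889 (0.832%, 0.616 to 1.099) had one within 200 bp, against 9.53% (range 8.75 to 10.4) in 20 random placements. Pseudogenes were also low, with 5 of 330 (1.52%, 0.494 to 3.50) against 6.11% (4.24 to 7.58). How well reads map to such copies was not examined, so these low shares need not reflect binding. The ncRNA genes were above random, with 453 of 3289 (13.8%, 12.6 to 14.998) against 8.11% (7.57 to 8.57). The placements were not matched on protein-coding promoters, so this excess was not separated from the excess of summits there. The tRNA genes, with 11 of 290 (3.79%, 1.91 to 6.69) against 3.09%, and the snoRNA and snRNA genes stayed within the random range.

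The replicates differed in a small part of the strongest 8015 of their 30000 peaks. Of the strongest 8015 peaks of replicate 2, 315 overlapped no replicate 3 peak, and 56.2% (50.5 to 61.7) of them were in promoters. Of those of replicate 3, 141 overlapped no replicate 2 peak, and 30.5% (23.03 to 38.8) were in promoters (Fisher's exact test between the sets, p = 3.6e-07). In the main draw of matched windows, over 8133 words of 7 bases held by at least 50 of them, the highest folds were 3.38 for CGCTCTC, at 1.77% of summits against 0.524%, and 3.38 for CGCTCGC, at 0.911% against 0.269%. Over 11 draws the fold ran from 3.35 to 3.68 for CGCTCTC and from 2.91 to 3.99 for CTCGCTC, while CGCTCGC was not drawn again, so no order among the 3 words is set.

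The ETS word was less frequent at summits than in flanks. Low G+C content of the summit windows may account for part of the gap, since the fold rose from 0.611 against flanks to 0.797 against matched windows. The summit share of 2.45% (2.12 to 2.81) still lay below the matched share in every draw, 2.83% to 3.16% (fold 0.775 to 0.863). It also lay below the share in windows with equal numbers of G and C bases (fold 0.816). The draws renewed only the background and all used the same summits, so they are not independent support. These values argue against G+C content as the whole cause, although the adjusted Fisher's exact test passed in 8 of the 11 draws. For misplaced summits, the highest share 100 to 300 bp away was 1.07 times that at 400 bp, which gives no sign of a shift by a common distance. Words spread over these distances would raise each window only a little, so misplaced summits are not excluded. The control word showed a gap of the same kind, 0.772 against matched windows and 0.788 at equal numbers of G and C bases. The deficit may therefore not concern ETS sites as such, and no biological explanation was tested.

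Summits sat in short A/T-rich stretches, with 85.0% of summit windows below their own flanks in G+C content. A preference of the libraries for A/T-rich fragments alone would give promoters and intergenic sequence the same density at the same G+C content. The measured ratio was 3.82 (3.59 to 4.07), which argues against such a preference acting alone. A higher promoter density was likely beforehand, since summits stood at 2.68 times random placement in promoters and 0.751 times in intergenic sequence. How well reads map to intergenic sequence was not examined, and a preference combined with other causes is not excluded. Soft-masked bases, as a measure of repeats, made up 26.2% (25.7 to 26.6) of summit windows against 33.0% in matched windows, a ratio of 0.794. Mapping of reads to repeats was not examined, and poor mapping could lower this share whatever the cause. The share also pools interspersed and simple repeats. In the main draw the GAGA word was higher at summits, with 1.71% against 0.626% in matched windows. The CA repeat stood at 1.51% against 1.20% and passed as higher in 5 of 11 draws. The share therefore does not decide whether repeats contribute. An effect of base composition acting within open chromatin stays open, because summit density fell from 831 per Mb at 15 to 20% G+C to 88.5 at 40 to 45% in promoters and from 233 to 9.34 in intergenic sequence, and no biological explanation was tested.

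The replicate 2 peaks at Ets96B that the other lists lack could come from extra copies of the locus on the transgene. Within 20 kb of Ets96B there were 3 replicate 2 peaks missing from the replicate 3 and pooled lists, of 4517 such peaks in all. The median gene had 2, and 68.8% of protein-coding genes had fewer than Ets96B. The count is above the median and short of the 95% set before it was made. It took no account of peak strength. The peaks at 24795227 and 24798810 ranked 3687 and 3495 in replicate 2. Of the strongest 8015 replicate 2 peaks, only 224 overlapped neither a replicate 3 peak nor a pooled peak. Whether peaks this strong gather at Ets96B was not tested, so extra copies and the background of such peaks cannot be told apart here.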
